A study of Homo sapiens with 2 samples.

How the data were processed

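RNA was sequenced from 2 cultures of a human cell line labelled MKN-45, each stably transfected under puromycin, with an empty vector or with a circAGO2 expression vector, 1 library per group. Per the labels, RNA was extracted with TRIzol, libraries were built with a TruSeq RNA kit, and paired-end reads of 100 bp were generated on an Illumina HiSeq sequencer. Per the series' design text, reads per gene were counted with HTSeq 0.6.0. The submitters' processing notes name TopHat2 2.0.9, Bowtie2 2.0.6 and the genome build hg38, without saying what each was used for. The authors deposited 1 value per gene and library, a normalised signal and not raw counts, and the step that scaled it is not given in the sources used here. Whether counting used strand is also not given, so reads of overlapping genes on opposite strands could not be separated.

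Every deposited value was a whole multiple of 1 step per library. Dividing by the step gave whole reads for 100% of values within a tolerance of 0.1 reads, the largest deviation being 0.0051 reads. The recovered totals were 21061044 reads for the empty vector and 20961062 for circAGO2. Raw counts had been assumed when the comparisons were laid out; the recovered reads were used in their place. The columns used were those of the 2 samples, and no count test was run on the recovered reads, since 1 library per group leaves no spread to test against. Reads were scaled with TMM factors from edgeR 4.0.16. These factors, 0.99501 for the empty vector and 1.00501 for circAGO2, equal the recovered steps to that precision. The deposited values thus match TMM-scaled counts. The ratio of scaled counts carries a 95% exact Clopper-Pearson interval, which covers counting error only, and a count of 0 was set to a floor of 3 counts. Genes with 20 or more reads summed over both libraries were kept. A gene counted as higher or lower at a ratio of 2 or more, or 0.5 or less, with an interval excluding 1. Gene names, positions and transcript sequences came from GENCODE 29 (Ensembl 94, GRCh38), in which 29405 of the 30067 listed genes have a record and 662 do not.

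The comparisons, the gene lists and 44 alternative settings were chosen before the data were examined. The genes named are AGO2 and ELAVL1, 11 of the 12 protein-coding genes with the largest increase and the 12 with the largest decrease among those with a mean scaled count of 100 or more, and up to 4 members with a mean of 20 or more in each list that stood apart and in the lists of the small RNA pathway, AU-rich element binding proteins and mRNAs that bind HuR. All were ranked by the interval bound nearest to 1, and 2 of the genes picked this way are not described in the text. Other genes named were chosen after their values were seen. Of 42 lists, 39 had 5 or more genes past the filter. A list's median log2 ratio was placed among 10000 random lists of the same size drawn within 20 bins of mean expression, and stood apart below the 2.5th or above the 97.5th percentile. Windows of 25 neighbouring genes with a mean of 50 or more were set against 1000 random gene orders. Genes with a 7-base site in the longest annotated 3' UTR (18 microRNA families, 4 control families and an AU-rich element) were set against 10000 random sets matched on expression and 3' UTR length.

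A trend of the ratio with transcript GC content was seen in the data, and 12 alternatives were added to the planned ones. Of these, 9 were chosen after seeing the trend or other results, and match random lists and sets on GC content or length, remove a running median over 40 GC points, or limit random lists to protein-coding genes. The other 3 keep the first form of the site comparison. Matched random lists used 4 classes each of GC content and length. Members of a list were not removed from the genes its random lists were drawn from. Where GC content was matched for sites, expression and 3' UTR length were in 5 bins each in place of 10. The main form of the site comparison was itself chosen after results were seen. In the first form, random sets were drawn from genes without the site. It was replaced after it had been run on these libraries, because in simulations without a difference it left 15 of 115 sites outside the range. The form now used, which shuffles site labels among matched genes, left 8 of 115 outside. Results of both forms are given with the alternatives. Explanations of the lower histone genes were also tested and then set aside to keep to 3 patterns. The test of S phase on DNA replication genes had first met its criterion, which was made stricter after the value was seen, so the values are printed without an explanation. Whether a few genes alone made the immediate early and YAP lists lower was first tested with the 3 members beyond 1.5-fold left out; a median over 44 genes could hardly change by that, and a count of intervals replaced it.

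The steps were tested on simulated data. In 20 simulations of counting noise alone over the 30067 listed genes, the size rule called on average 45.2 genes higher and 41.4 lower, at most 107 in all. Among genes with 20 or more simulated reads, the interval held a ratio of 1 in 95.7% of cases. Genes changed 2-fold were recovered in 43.3% of cases with a mean under 100 and 53.0% with a mean of 100 or more. For 3-fold these shares were 86.5% and 99.9%, and for 4-fold 96.6% and 100%. Of 390 lists simulated without a difference, 23 lay outside the random range. A GC slope alone put 18 sites outside with plain matching and 0 with transcript GC content matched. The slope put in was steeper than the trend in these libraries, so the 18 is not what their trend alone would give. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3; DESeq2 1.42.0 gave size factors for 1 alternative scaling only. circAGO2 itself is given no value, since a gene count does not identify circular RNA.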

Results

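Gene expression was measured by RNA sequencing in MKN-45, named in the labels as a human gastric cancer cell line, after stable transfection with a circAGO2 expression vector or with the empty vector. circAGO2 is a circular RNA from AGO2, the gene of the Argonaute protein that carries microRNAs. There was 1 library per group, from cells at passages 15 to 18. The reads assigned to genes came to 21061044 in the empty vector library and 20961062 in the circAGO2 library. Of the 30067 genes listed, 16862 had 20 or more reads summed over both libraries, and 12785 of these were protein-coding. With 1 library per group there is no replicate check of any difference, and no p-value, SD or SE is given. Ranges in brackets are 95% exact counting intervals of the ratio of scaled counts, circAGO2 over empty vector. PCR reads without molecular identifiers are not independent molecules, so these intervals cover counting error only.

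The comparison asked how gene expression in cells overexpressing circAGO2 differed from that in empty vector cells. AGO2 itself (ENSG00000123908, chromosome 8, 140520156 to 140635619, minus strand, GRCh38) had 4286 reads in the empty vector library and 4458 in the circAGO2 library. Its ratio was 1.05 (1.01 to 1.10). A gene count does not identify circular RNA, so this is not a value for circAGO2 and does not check the transfection. ELAVL1, which encodes HuR, an RNA-binding protein of AU-rich mRNAs that circAGO2 is known to bind, had 2256 and 2208 reads, a ratio of 0.989 (0.932 to 1.05). Neither gene reached the ratio of 2 set for a difference.

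The libraries were close for well-covered genes. Among the 11434 genes with a mean scaled count of 100 or more, 99.8% lay within 1.5-fold. Spearman's rho of the scaled counts across these genes, which are not independent replicates, was 0.996. By a ratio of 2 or more in either direction with an interval excluding 1, 99 genes were higher and 126 lower in circAGO2 cells, 39 and 48 of them protein-coding. All but 4 of these genes had a mean scaled count below 100, where counting noise is large. Simulated libraries with counting noise alone gave on average 45.2 genes higher and 41.4 lower by the same rule, and no gene with a mean of 100 or more. They leave out spread beyond counting, so more calls than these are no measure of an effect. At means of 20 to 50, the scaled median absolute deviation of log2 ratios across genes was 0.449, against 0.372 from counting. The 4 well-covered genes were JUN and 3 features named after their values were seen. 7SK (ENSG00000202198, chromosome 6, 52995620 to 52995950, plus strand), a small nuclear RNA made by RNA polymerase III that restrains transcription elongation, had 454 reads in empty vector cells and 48 in circAGO2 cells, a ratio of 0.107 (0.0776 to 0.144). ENSG00000277105 had 27 and 2372 reads, a ratio of 88.7 (60.8 to 135). ENSG00000276924 had 1286 and 357 reads, a ratio of 0.280 (0.249 to 0.316). These identifiers have no symbol in the annotation used here, and reads shared with near-identical copies were not excluded.

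**Figure D1:**
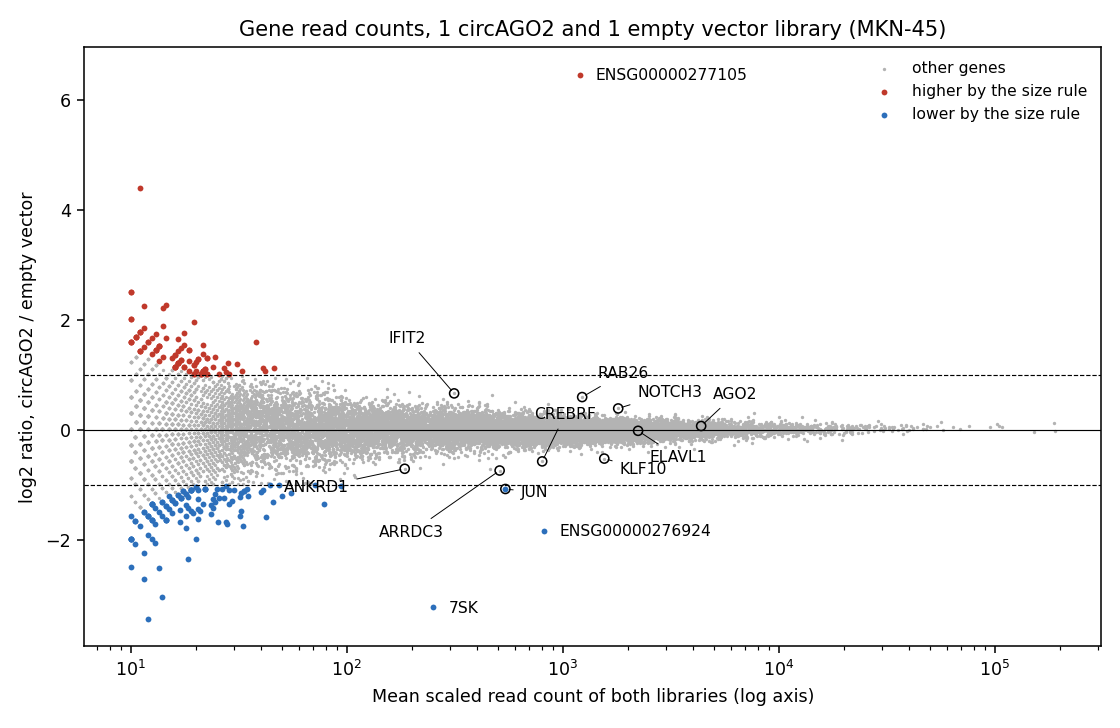
Each point is a gene with 20 or more reads summed over both libraries; the x axis is its mean scaled read count (log axis) and the y axis the log2 ratio of circAGO2 to empty vector, from 1 library each. Dashed lines mark ratios of 2 and 0.5; 99 genes (red) were higher and 126 (blue) lower by the size rule, nearly all at low counts, and named genes are circled.

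Among protein-coding genes with a mean scaled count of 100 or more, the largest decrease was in JUN (ENSG00000177606, chromosome 1, 58780788 to 58784327, minus strand), an AP-1 transcription factor subunit. JUN had 739 reads in empty vector cells and 347 in circAGO2 cells, a ratio of 0.474 (0.416 to 0.540). It was followed by ARRDC3, an arrestin-domain protein (ratio 0.599, 0.526 to 0.681), DNAH11, an axonemal dynein heavy chain (0.552, 0.412 to 0.733), and CREBRF, a regulator of CREB3 (0.672, 0.607 to 0.743). KLF10, a transcription factor induced by TGF-beta, had 1844 and 1271 reads, a ratio of 0.696 (0.648 to 0.748). SNAPC1, a subunit of the complex that activates small nuclear RNA genes, had a ratio of 0.615 (0.504 to 0.749). Ratios of GPR75, ANKRD1, DOP1A, SGCB, CSRNP1 and PARD6B lay between 0.564 and 0.708. Of these 12 genes, ranked by the interval bound nearest to 1, JUN was below the ratio of 0.5.

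On the other side, RAB26, a small GTPase of vesicle traffic, had 983 reads in empty vector cells and 1473 in circAGO2 cells, a ratio of 1.51 (1.40 to 1.64). IFIT2 and IFIT1, antiviral proteins induced by interferon, had ratios of 1.59 (1.35 to 1.87) and 1.43 (1.24 to 1.65). PHOSPHO1, a phosphatase of bone mineralisation, had the highest ratio of the 11 genes named here at 1.67 (1.32 to 2.12), on 115 and 190 reads. MXRA8, GIPR, ESPN, GSTA4, PTGDS and COL15A1 lay between 1.39 and 1.61. NOTCH3, a Notch receptor, had 1570 and 2038 reads, a ratio of 1.31 (1.23 to 1.40). None of these 11 genes, ranked in the same way, reached a ratio of 2.

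Of 39 gene lists with at least 5 members past the filter, 15 had a median log2 ratio outside the central 95% of 10000 random lists matched on expression, where chance gives 1.95. Ratios also followed the GC content of transcripts (values with the 3' UTR sites), so each of these lists is given a second percentile from random lists matched on GC content and length as well. These percentiles describe 2 libraries. They do not test the conditions, since genes of a list can move together between any pair of cultures. Over all 16862 genes past the filter, intervals of 1849 lay above a ratio of 1 and of 1852 below. Simulated counting noise alone left 95.7% of intervals holding 1, so the libraries differed by more than counting error. At means of 3000 or more, the scaled median absolute deviation of log2 ratios across genes was 0.078, against 0.029 from counting. The intervals do not cover this extra spread.

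Interferon response genes had the highest median among the lists that stood apart, 0.15 on the log2 scale over 29 genes (percentile 99.99, and 99.99 with GC content and length matched). Intervals of 12 members lay above a ratio of 1, 1 below, and 16 held 1. Besides IFIT2 and IFIT1, these included IFI6 (ratio 1.27, 1.12 to 1.45) and HERC5, a ligase for the ubiquitin-like protein ISG15 (1.52, 1.12 to 2.08). Genes of cholesterol synthesis had a median of 0.11 over 24 genes, above all random lists by either matching. Of these, 15 had intervals above 1 and 1 below. Intervals lay farthest from 1 for TM7SF2 (1.34, 1.13 to 1.59), a sterol reductase, and for MVD (1.20, 1.12 to 1.29). HMGCS1 (1.14, 1.10 to 1.19) and FDFT1 (1.14, 1.10 to 1.17) came next. Like MVD, they are enzymes of the mevalonate pathway and squalene synthesis. Matrix proteases and integrins had a median of 0.11 over 21 genes (percentiles 99.97 and 99.99). ITGB4, the integrin of hemidesmosomes, had a ratio of 1.26 (1.18 to 1.34), ITGA2 1.24 (1.09 to 1.41), the protease inhibitor TIMP3 1.14 (1.08 to 1.21) and ITGA3 1.14 (1.08 to 1.20). In this list 8 intervals lay above 1 and 1 below. The log2 ratio of MVD went from 0.26 to 0.16, and that of ITGA3 from 0.19 to 0.10, with the GC trend removed.

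Efflux transporters (median 0.12 over 9 genes, percentiles 99.19 and 99.02) and genes of hypoxia and glycolysis (median 0.07 over 30 genes, percentiles 99.96 and 99.33) were also higher by both matchings. MVP, the major vault protein, had a ratio of 1.15 (1.08 to 1.21), ABCC3 1.25 (1.08 to 1.45), SLC29A1 1.17 (1.08 to 1.28) and ABCC5 1.09 (1.02 to 1.17). With the mean in place of the median, the transporters were at percentile 95.88 and no longer stood apart. Among hypoxia and glycolysis genes, 17 intervals lay above 1 and 3 below. CA12, a carbonic anhydrase, had a ratio of 1.39 (1.18 to 1.63), the lactate transporter SLC16A3 1.17 (1.12 to 1.23), the aldolase ALDOC 1.22 (1.10 to 1.35) and the phosphofructokinase PFKL 1.14 (1.09 to 1.18). Ribosomal protein genes (median 0.05 over 41 genes, percentile 99.78) and mRNAs of the mitochondrial genome (median 0.06 over 13 genes, percentile 97.61) were higher than lists matched on expression alone. With GC content and length matched they lay inside the random range, at percentiles 86.44 and 94.28. List members were not removed from the genes drawn, and classes of short, highly expressed genes can hold many of them. This matching thus cannot tell whether GC content or length accounts for the shift. With the GC trend removed, the median went from 0.05 to 0.03 for ribosomal proteins and from 0.06 to 0.08 for mitochondrial mRNAs. RPL35 (1.11, 1.08 to 1.13), RPS3 (1.08, 1.07 to 1.09) and RPL8 (1.06, 1.05 to 1.08) had the intervals farthest from 1 among ribosomal proteins. These genes have pseudogene copies that can share reads. With the GC trend removed, the log2 ratio of RPL8 went from 0.09 to -0.01, RPL35 from 0.15 to 0.04, PFKL from 0.18 to 0.08, MVP from 0.20 to 0.11 and SLC16A3 from 0.23 to 0.14. MT-ND4L had a ratio of 1.18 (1.14 to 1.22), MT-CO1 1.09 (1.08 to 1.10), MT-CO2 1.08 (1.07 to 1.09) and MT-ATP6 1.05 (1.04 to 1.07). The log2 ratio of MT-ATP6 rose from 0.07 to 0.10 with the GC trend removed. Mitochondrial mRNAs also lay inside the range with the filters of 10 or more and 100 or more counts, at percentiles 97.23 and 97.02. Size factors from DESeq2 shift all log2 ratios alike, so the percentile of 97.33 found with them reflects a new random draw and bins.

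Replication-dependent histone genes had the lowest median of all lists, -0.33 over 15 genes, below nearly all random lists by both matchings (percentiles 0.01 and 0). With the filter of 100 or more counts the median was -0.15 over 9 genes (percentile 1.2), and the mean in place of the median was -0.51. Their main mRNAs end in a stem-loop in place of a poly(A) tail. Members of this family are near-identical and can share reads. H4C3 had 45 and 20 reads, a ratio of 0.449 (0.251 to 0.776), H1-2 787 and 618 reads, a ratio of 0.793 (0.713 to 0.882), HIST1H3B 0.505 (0.275 to 0.898) and H2BC8 0.761 (0.622 to 0.929). In this list 5 intervals lay below 1 and none above. Immediate early genes, which are induced within minutes by growth factors and stress, had a median of -0.09 over 23 genes (percentiles 0.73 and 0.01). JUN and KLF10 led the list, and the stress-induced factor ATF3 had a ratio of 0.758 (0.705 to 0.815). NR4A1, an orphan nuclear receptor, went against them with a ratio of 1.20 (1.11 to 1.30). Of the 23, 7 intervals lay below 1 and 2 above. Targets of the coactivator YAP had a median of -0.09 over 21 genes (percentiles 0.11 and 0), with 9 intervals below 1 and 2 above. Among them were ANKRD1 (0.612, 0.493 to 0.758), GADD45B (0.699, 0.594 to 0.822), AJUBA (0.835, 0.795 to 0.876) and CCN1 (0.844, 0.804 to 0.886).

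Targets of p53 had a median of -0.07 over 22 genes (percentiles 0.79 and 0.07). MDM2, the ubiquitin ligase that degrades p53, had a ratio of 0.802 (0.762 to 0.844), BTG2 0.840 (0.758 to 0.931), RRM2B 0.898 (0.839 to 0.961) and AEN 0.885 (0.812 to 0.965). CDKN1A, which encodes the p53-induced inhibitor p21, had 3484 and 3296 reads, and its interval held 1. Unfolded protein response genes had a median of -0.05 over 25 genes (percentiles 2.44 and 0.79), with 9 intervals below 1 and 3 above. PPP1R15A had a ratio of 0.755 (0.701 to 0.813) and HERPUD1 0.879 (0.813 to 0.950), whereas ASNS, asparagine synthetase, had 1.20 (1.05 to 1.37). The unfolded protein response list came inside its range with the filter of 10 counts (percentile 2.74), with the mean (3.39) and with coding genes alone as background (2.67). Its percentile of 2.72 with DESeq2 size factors differs only by the random draw and bins, since that scaling shifts all log2 ratios alike. Mitosis genes had a median of -0.05 over 25 genes (percentile 1.66), and lay inside the range at 2.69 with GC content and length matched. BUB1B had a ratio of 0.852 (0.789 to 0.919), CKAP2 0.918 (0.866 to 0.973), CENPF 0.954 (0.934 to 0.974) and MKI67 0.949 (0.922 to 0.977). MET and genes beside it on 7q31, a locus known to be amplified in MKN-45, had a median of -0.10 over 10 genes (percentile 0.76), at 3.02 with GC content and length matched. MET itself (chromosome 7, 116672390 to 116798386) had 7544 and 6542 reads, a ratio of 0.876 (0.847 to 0.906). CAV1 had 0.913 (0.879 to 0.948), TES 0.935 (0.892 to 0.980) and CAV2 0.930 (0.882 to 0.981). The mean of this list gave percentile 26.5. Removing the GC trend took the log2 ratio of CENPF from -0.07 to -0.02, CKAP2 from -0.12 to -0.05, RRM2B from -0.16 to -0.09 and CAV2 from -0.10 to -0.06.

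**Figure D2:**
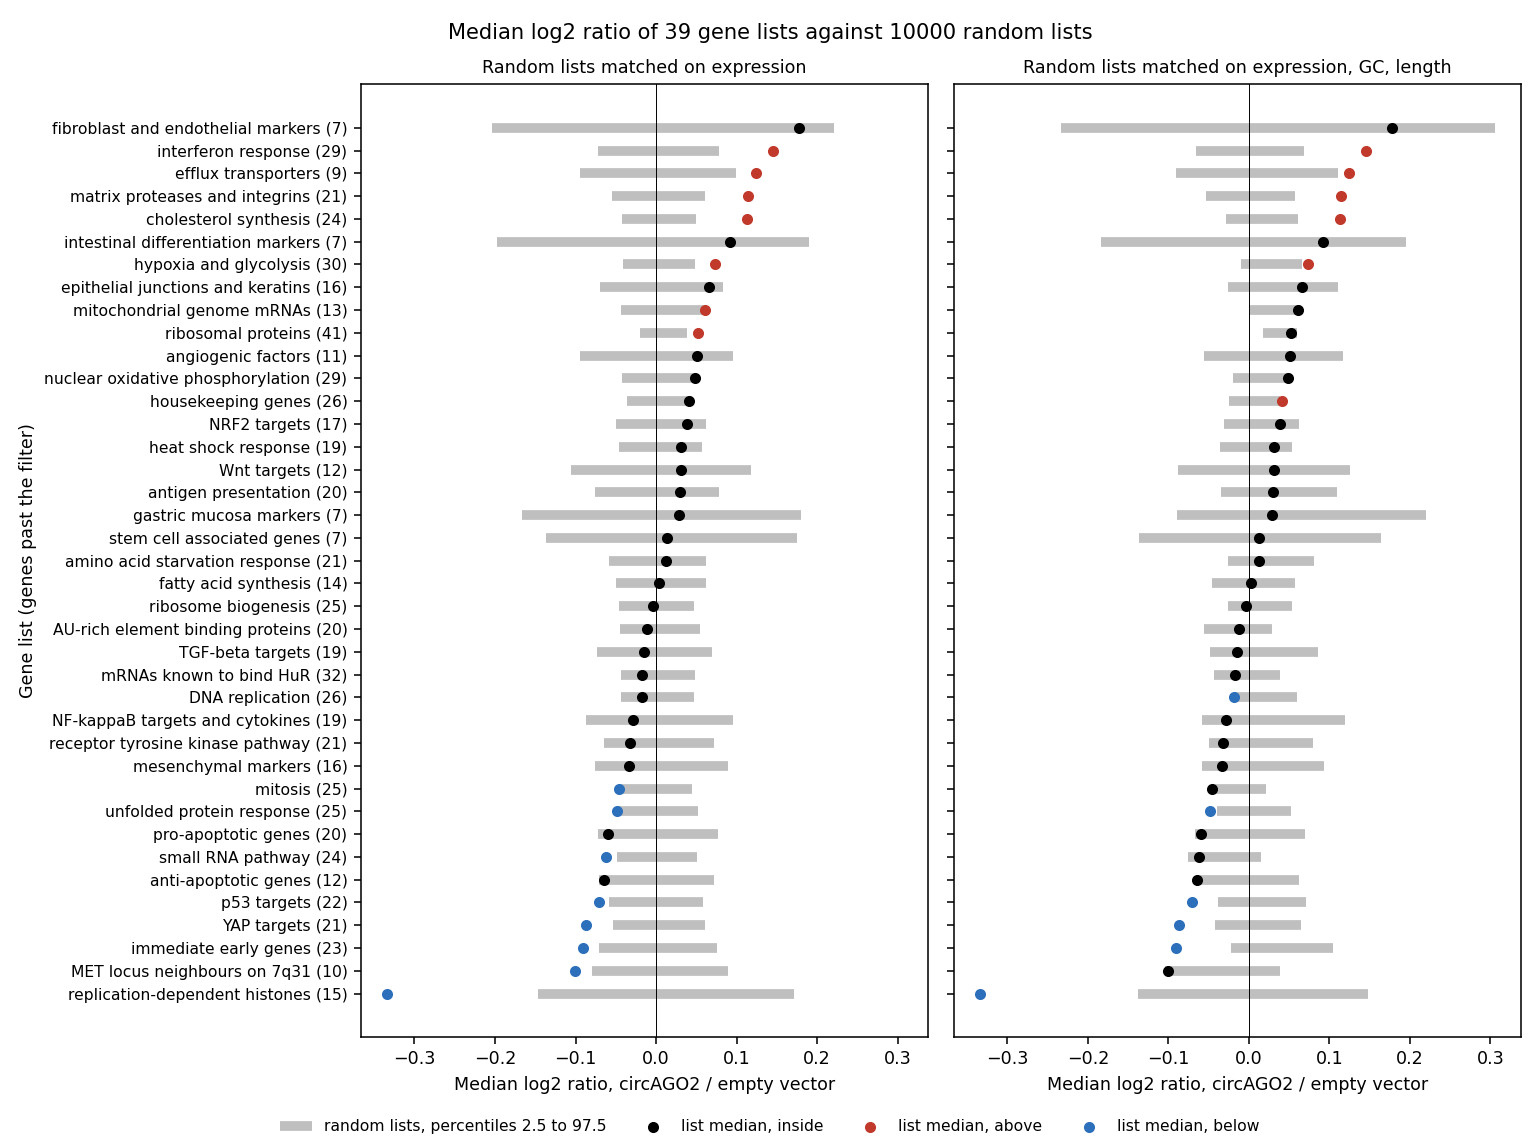
Points are the median log2 ratios, circAGO2 over empty vector (x axis), of 39 gene lists (y axis, genes past the filter in brackets), from 1 library each. Grey bars span the central 95% of 10000 random lists matched on expression (left) or also on transcript GC content and length (right); 15 lists lie outside on the left and 12 on the right.

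Of the 3 lists closest to the known functions of AGO2 and HuR, 1 was outside its range by expression matching. Small RNA pathway genes had a median of -0.06 over 24 genes (percentile 0.71), which lay inside the random range, at percentile 8.37, once GC content and length were matched. DCP1A, a decapping factor, had a ratio of 0.805 (0.728 to 0.889), TNRC6A, the Argonaute partner GW182, 0.859 (0.812 to 0.909), PAN3, a deadenylase subunit, 0.827 (0.752 to 0.910) and AGO4 0.861 (0.771 to 0.961). Of the 24 members, 8 intervals lay below 1, 3 above and 13 held 1. AU-rich element binding proteins had a median of -0.01 over 20 genes (percentile 24.9). PUM2 had a ratio of 0.869 (0.828 to 0.912), RBM38 1.22 (1.06 to 1.40), AUH 1.28 (1.05 to 1.58) and HNRNPD 1.06 (1.03 to 1.09). The mRNAs known to bind HuR had a median of -0.02 over 32 genes (percentile 19.6), with 7 intervals below 1, 5 above and 20 holding 1. SNAI1, an inducer of epithelial-mesenchymal transition, had 120 and 77 reads, a ratio of 0.648 (0.480 to 0.870). SIRT1 had a ratio of 0.840 (0.790 to 0.892) and the apoptosis inhibitor XIAP 0.896 (0.844 to 0.951), and the cytokine TGFB1 1.23 (1.10 to 1.37). When the GC trend was removed, the log2 ratio of HNRNPD went from 0.08 to 0.15, RBM38 from 0.29 to 0.18, TGFB1 from 0.30 to 0.19 and XIAP from -0.16 to -0.10. No member of these 3 lists reached a ratio of 2 or 0.5.

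Lists of epithelial junctions and keratins (median 0.07 over 16 genes, percentile 94.0), mesenchymal markers (-0.03 over 16 genes, percentile 16.2) and gastric mucosa markers (0.03 over 7 genes, percentile 60.9) lay inside their random ranges. With the mean in place of the median, mesenchymal markers were at percentile 1.55. In the same libraries EPCAM had 25 and 21 reads and CEACAM5 1 and 0, whereas KRT8 had 29927 and 31250. Markers of fibroblasts and endothelium had a median of 0.18 over 7 genes (percentile 95.2), and markers of blood cells left 2 genes past the filter and of neurons and hepatocytes 4. DNA replication genes (median -0.02 over 26 genes) were at percentile 19.9 and, with GC content and length matched, at 2.1. Housekeeping genes (median 0.04 over 26 genes) were at 96.2 and 98.1, and genes of nuclear oxidative phosphorylation (median 0.05 over 29 genes) at 97.3 and 96.1.

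Whether mRNAs with microRNA sites or AU-rich elements differed was examined in 11201 genes with an annotated 3' UTR and a mean scaled count of 50 or more. Genes with a TATTTAT element in the longest 3' UTR (4036 genes) had a median log2 ratio of -0.04, which was 0.040 below that of genes matched on expression and 3' UTR length without the element. The 18 microRNA sites gave differences between -0.029 (miR-200b family, CAGTATT) and 0.040 (miR-34, CACTGCC), and 12 of them lay outside the range of 10000 random sets, 8 lower and 4 higher. Of the sites of 4 control microRNAs restricted to other tissues, 3 lay outside, all higher. With the shortest 3' UTR, or with a mean scaled count of 200 or more, 1 of these 4 lay outside, against 9 and 12 of the 18. Ratios followed transcript GC content across genes (Spearman's rho 0.414, over 11406 genes that are not independent replicates). The median log2 ratio went from -0.07 in the tenth of genes with the lowest GC content to 0.10 in the tenth with the highest. With transcript GC content matched as well, and expression and 3' UTR length in 5 bins in place of 10, 7 of the 23 sites lay outside. No difference was larger in size than that of the AU-rich element, -0.015 (percentile 0). Ratios also fell with 3' UTR length across genes (Spearman's rho -0.209), which the coarser bins match less closely. The 7 sites outside were the AU-rich element, miR-200b family, miR-30, miR-19 and miR-23 on the lower side, and miR-34 (0.012) and the control miR-9 on the higher side. With 3' UTR GC content matched instead, the AU-rich element remained lower by 0.013 (percentile 0.035). The miR-200b family (percentile 6.15) and miR-30 (4.79) then lay inside the range, and miR-29 (0.345) came to lie below it. Sites of miR-19, miR-23, miR-34 and miR-9 stayed outside on the same side.

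**Figure D3:**
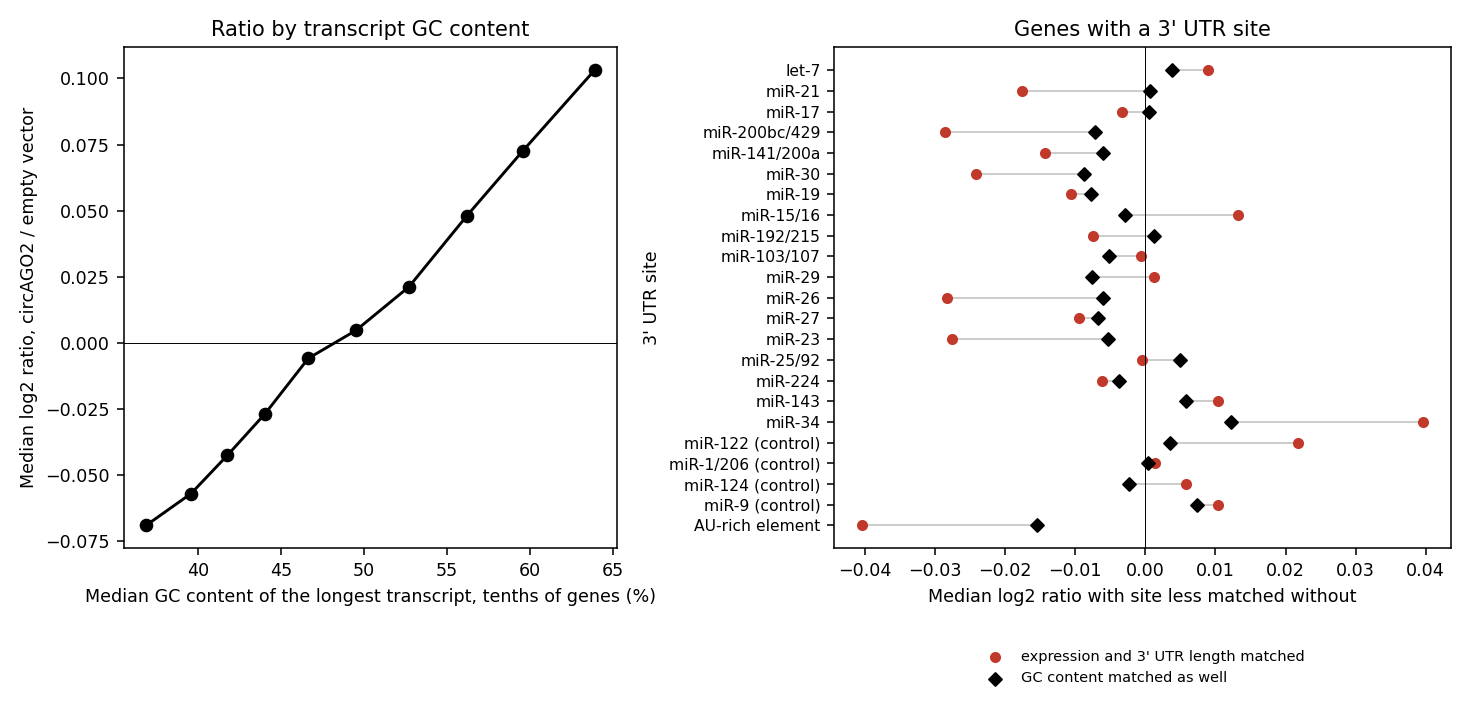
Left, the median log2 ratio of circAGO2 to empty vector (y axis) in 10 equal groups of genes by GC content of the longest transcript (x axis, %), going from -0.07 to 0.10. Right, for each 3' UTR site (y axis), the median log2 ratio of genes with the site less that of matched genes without it (x axis). Matching was on expression and 3' UTR length (red), or in coarser bins of both and also on transcript GC content (black). In black, the AU-rich element lies farthest from 0, at -0.015.

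Stretches of neighbouring genes were compared as a copy number difference between the stable lines would shift them together. Among 12182 windows of 25 consecutive genes with a mean scaled count of 50 or more, 10 had a median log2 ratio beyond the level of 0.16 that the highest window exceeded in 5% of random gene orders. They formed 2 stretches. On chromosome 19, 36114289 to 38229714 (TBCB to DPF1), which holds a cluster of zinc finger genes with a median transcript GC content of 39.4%, the lowest window had a median of -0.22, a ratio of 0.861. At the end of the short arm of chromosome 1, 629640 to 1309609, where median transcript GC content was 63.4%, the highest window had a median of 0.19, a ratio of 1.14. With the GC trend removed, the chromosome 1 stretch was no longer beyond the random orders, and the chromosome 19 stretch kept a median of -0.15. With 51 genes per window, or with genes of a mean of 200 or more, nothing on the lower side of chromosome 19 lay beyond random orders. Of the windows of 51 genes, 144 lay beyond, 137 of them higher. The highest windows of these stretches had a median transcript GC content between 56.9% and 64.6%. The 7 lower windows formed a stretch on chromosome 6, 25279078 to 30557174, which spans the histone cluster. With the GC trend removed and 25 genes per window, a further 2 stretches lay beyond random orders on the lower side. They were at chromosome 19, 42325609 to 44134816, and at the same histone cluster on chromosome 6, 26158146 to 28137293. Zinc finger and histone genes of these clusters are paralogues that can share reads. No window of 25 genes differed by 1.5-fold.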

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

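The alternatives with GC content and with protein-coding random lists were chosen after the results were seen, as was the main form of the site comparison, which replaced the form run first; the others were planned. The count of genes by the size rule depended on the filter and on the ratio set, as genes with few reads make up most of it. Genes higher numbered 153, 1 and 203 with filters of 10, 100 and 1 or more counts, against 99, and genes lower 188, 8 and 230, against 126. A ratio of 1.5 gave 223 higher and 235 lower, a ratio of 4 gave 9 and 10, a whole interval beyond 2 gave 2 and 5, and coding genes alone 39 and 48. Among the other scalings, DESeq2 size factors moved the split farthest, to 89 higher and 139 lower. With the GC trend removed, 90 genes were higher and 134 lower, of which 85 and 119 were among those called before.

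Of the 88 genes set by the naming rule, AGO2 and ELAVL1 included, 13 left their counting interval with the GC trend removed and RPL8 turned to -0.01; 2 left it with DESeq2 size factors and 0 with the other scalings, thinning or 5 added counts. Of the 15 lists that stood apart, 8 kept their side in all 6 settings and 7 lost it in some. Nuclear oxidative phosphorylation came to stand apart in 4 settings, at percentile 97.57 with DESeq2 size factors, 97.96 and 98.62 with filters of 10 and 100 counts and 97.92 with protein-coding random lists. DESeq2 size factors shift all log2 ratios alike, so lists that crossed a bound in that setting did so by the random draw and bins. The largest window median turned positive, to 0.154 on chromosome 17 with 51 genes per window and to 0.146 on chromosome 1 with a mean of 200 or more, and the chromosome 19 stretch was lost in both; the cause was not tested.

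Of 23 sites, 16 lay outside the random range, 7 with transcript GC content matched and 6 with 3' UTR GC content matched. With sets drawn from genes without the site, the form run first, these counts were 15, 10 and 11, and miR-15/16 turned from higher to lower at percentile 0.85 with 3' UTR GC content matched; the cause was not tested.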

Other observations

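Expression in both libraries was that of a keratin-rich cell. KRT8 had 29927 reads in empty vector cells and 31250 in circAGO2 cells, KRT18 5085 and 5475, and JUP, the junction protein plakoglobin, 16940 and 18196. EGFR had 18166 and 16982 reads and ranked 106 of all genes by mean, above MET, with 7544 and 6542 reads and rank 437. ALPP, placental alkaline phosphatase, had 9027 and 9289 reads, and the mesenchymal genes VIM 5173 and 5152 and CDH2 558 and 500. The epithelial genes EPCAM (25 and 21), CDH1 (93 and 87), GRHL2 (2 and 2) and RAB25 (1 and 0) had few reads, whereas CLDN7, an epithelial claudin, had 1085 and 1290.

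Genes whose main RNAs lack a poly(A) tail differed in their ratios, though read counts do not show whether a tail was present. Reads of 15 histone genes came to 3794 and 3348, a ratio of 0.891 (0.851 to 0.934), and the list was at percentile 0 with GC content and length matched. For 1357 other genes of small structured RNAs the reads came to 4021 and 3930, a ratio of 0.987 (0.944 to 1.03), while 7SK had a ratio of 0.107. DNA replication genes, which like histones are used in S phase, were at percentile 19.9 and, with GC content and length matched, at 2.1.

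Tests of GC content as the whole cause, of a difference between any pair of cultures, of a few genes alone, and both on line identity were chosen after the result was seen. The others were set before the matched lists were run, though the trend with GC content over all genes was already known.

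More lists stood apart than chance gives, 15 of 39. Noncoding genes in the random lists are argued against, since 14 of the 15 kept their side with protein-coding random lists. GC content or length as the whole cause is also argued against, since 12 lists stood apart with both matched, where chance gives at most 5. As a part of the pattern GC content and length stay open too, since 10 of the 15 kept their side, between the bounds set for and against. Whether any pair of cultures of this line would differ as much cannot be told apart from an effect of circAGO2, since there are 0 pairs of libraries within a group.

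Immediate early genes and YAP targets were lower together, with a pooled median log2 ratio of -0.09 over 44 genes. A trend with GC content or length is argued against, as the pooled median was at percentile 0 with both matched. The lower ratios were not confined to a few genes, as intervals of 16 of the 44 lay below a ratio of 1 and of 4 above. Matched random lists had at most 14 below. The 16 are the 7 and 9 intervals already seen in the 2 lists, which were picked as low, so this count is no separate test. An effect of circAGO2 and a difference between the cultures both stay open, untested, with 1 culture each.

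MKN-45 is known for amplified MET and for making carcinoembryonic antigen, the product of CEACAM5, yet CEACAM5 and EPCAM together had 47 reads over both libraries. A culture of another line than the one named may be the source, but these genes were singled out because of their low reads, so the 47 reads cannot also test it. Loss of epithelial genes during selection or passage could also lower them, although KRT8 kept a mean scaled count of 30592 and CLDN7 of 1188; neither explanation is excluded. Both libraries are alike in this. Apart from those on line identity and the S phase test set aside for the histone genes, no biological explanation was tested.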
